A study of Homo sapiens with 15 samples.

How the data were processed

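RPMI-8226 cells, an established human multiple myeloma line grown in RPMI 1640 medium with 10% fetal bovine serum, were treated with 100 nM KB528 for 1, 3, 6 or 24 h or with DMSO, and RNA was extracted with a Zymo kit and made into strand-specific mRNA libraries with NEB kits, per the labels. KB528 is named there as an inhibitor of the acetyltransferase activity of p300. The submitters' processing notes name STAR, featureCounts, FastQC and MultiQC and the genome build hg19, without versions or settings. The authors deposited 1 table of TPM values, with 26456 rows and 15 columns, in which each column sums to 1000000, so that lengths and library size are already divided out. Of its rows, 92 are ERCC spike-ins, which take 9.35% to 16.6% of the TPM of a library, and 26364 are genes. None are mitochondrially encoded. The columns of the DMSO group are named as untreated at 0 h in the table, while the sample titles say DMSO. They were matched by time and replicate number, and 0 columns were left unused. When the spike-ins were added, and how many counts lay behind the values, is not given in the sources used here.

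Because TPM keeps no depth, relative depth was taken from the low values. The ratios between libraries of the lowest values (up to 0.1 TPM) gave each library's depth relative to DMSO replicate 1, and the commonest single-read value of small RNA genes (396 of 703 genes) gave the absolute step. Of 17709 low values in 1580 genes, 94.0% were whole reads within 0.02 reads, which does not test the absolute step. The steps put 1 read in a transcript of 1000 bases at 0.0311 to 0.0458 TPM. Levels below about this rest on single reads, and counting limits the precision of low genes. Count models were not used, since TPM are not counts.

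Gene names, biotypes and gene spans came from the RefSeq annotation of GRCh38, in which 25198 gene rows (95.6%) were found by name. Transcript lengths came from GENCODE, as the longest protein-coding transcript of each name, or else its longest transcript. They can therefore exceed the length of the transcript that was expressed. No coordinates were used, since the deposited table was made on hg19. A transcript length was found for 97.5% of tested genes and a span for 98.3%.

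Choices made before the data were examined were the tests, the groups, the filter, the gene lists, the rule for named genes and most of the alternatives. Genes with a mean of at least 1 TPM over the 15 libraries were tested (12002, of which 394 are small RNA genes). That the ERCC rows stay out of the tests was decided after the table was seen. The values were tested as log2(TPM + 1) with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a variance trend), with all 15 libraries and 5 groups of 3 in 1 fit. Contrasts were each time against DMSO, consecutive times against each other, and a moderated F test over the time course. P-values were adjusted by the Benjamini-Hochberg method within each contrast, with a threshold of 0.05. A fold change on this scale understates the change of low genes. Lists with at least 5 tested members (32) were compared with all other tested genes by camera, from limma, with a preset inter-gene correlation of 0.01. Counts are also given adjusted over the list alone. Each printed estimated-correlation value is camera's adjusted p with the correlation estimated from the residuals, under which 0 lists were called at any time. Tables, checks and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

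At each time the named genes were 15 regulators fixed in advance, the 8 largest increases and the 8 largest decreases among called genes with a mean of at least 5 TPM whose 3 treated libraries all lay on the same side of the 3 DMSO libraries, and up to 4 members per called list with the smallest adjusted p in its direction. Chance puts 3 libraries on one side of 3 others for 10.0% of unchanged genes. Members of multi-copy families are named as uncertain. More genes are named than the 20 to 30 per time planned, all by this rule.

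The gene test was tested on simulated data, in which a few of the 12002 genes were changed by known folds, 50 per fold. Of 50 genes changed 1.5-fold it recovered 43 at 1 h, 48 at 3 h, 46 at 6 h and 42 at 24 h, and of 50 changed 1.25-fold 33, 37, 35 and 25. False calls were 4.35% of 184 calls at 1 h, 6.63% of 196 at 3 h, 5.76% of 191 at 6 h and 0.599% of 167 at 24 h. In the simulated list test at 6 h, camera and fry called the 1 list shifted by 0.5 log2 units and 0 of the others. Genes were simulated independently of each other, so this cannot show how often lists are falsely called when their genes vary together. Replicates correlated across genes with r between 0.995 and 0.998, and 0 pairs of libraries were identical.

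The alternatives planned were a pseudocount of 0.1, a filter of 5 TPM and no filter, median-ratio scaling over genes of at least 5 TPM, no variance trend, the replicate number as a block, only the compared groups in the fit, each library left out in turn, an estimated correlation in camera, and fry, a rotation test of whether a list's genes move one way. Scaling to the ERCC spike-ins, TPM rescaled without them, a loess correction for transcript length in each library and removal of small RNA genes were added after the data were seen. Fold changes shared between times were compared with 100 simulated draws of unchanged groups that shared a control group. In each draw that control group was taken at random from all 15 libraries.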

Results

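Polyadenylated RNA was measured by strand-specific RNA sequencing in RPMI-8226, an established human multiple myeloma cell line, treated with 100 nM KB528 for 1, 3, 6 or 24 h, or with DMSO at 0 h. Per the labels, KB528 inhibits the lysine acetyltransferase activity of p300, the coactivator encoded by EP300. The series title names the oncogenic activity of IRF4, a transcription factor on which myeloma cells depend. Each of the 5 groups held 3 libraries, 15 in all. Nothing in the labels says that the 3 libraries of a group came from separate cultures, so p-values measure only the spread between these libraries, which may be technical. The DMSO libraries were taken at 1 time, and every treated group was compared with them, so that handling and time in culture were not separated from KB528 at any time, 6 h and 24 h included. The deposited table gave transcript abundance (TPM) for 26364 gene rows and 92 spike-in rows. Total depth was not known. Steps in the low values put the relative depth of the libraries between 0.759 and 1.12 times that of DMSO replicate 1, and 1 read in a transcript of 1000 bases at 0.0311 to 0.0458 TPM. Between 11616 and 12356 genes per library had at least 1 TPM. Levels are means ± SD (n = 3), log2 fold changes are on the log2(TPM + 1) scale against DMSO, and adjusted p-values come from limma across 12002 genes.

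Of these genes, 2710 changed at 1 h (1802 higher and 908 lower), 6827 at 3 h (2991 higher and 3836 lower), 8272 at 6 h (5327 higher and 2945 lower) and 8564 at 24 h (6738 higher and 1826 lower). Over the time course 11229 genes changed in the moderated F test. The counts at 1 h moved when 1 library was left out. Without KB528 replicate 1, 2 or 3 in turn there were 1289, 1176 and 1275 higher and 679, 642 and 560 lower. The drop was similar whichever of them was left out. Without DMSO replicate 1, 2 or 3 in turn there were 1445, 1042 and 2898 higher and 531, 876 and 1022 lower. The median log2 fold change of all genes was 0.043 at 1 h, -0.042 at 3 h, 0.12 at 6 h and 0.23 at 24 h. The balance of higher and lower genes depended on the scaling. With median-ratio scaling there were 1858 higher and 1791 lower at 1 h, 3922 higher and 4504 lower at 6 h and 4458 higher and 3594 lower at 24 h. After correction for transcript length there were 1865 higher and 1770 lower at 1 h, 4179 higher and 3534 lower at 3 h and 4409 higher and 3727 lower at 24 h. Scaling to the spike-ins gave 411 higher and 2523 lower at 3 h and 4118 higher and 995 lower at 6 h. Relative to DMSO, median-ratio scaling shifted every gene by -0.16 at 6 h and -0.20 at 24 h, and spike-in scaling by -0.22 at 3 h and 0.19 at 6 h. The spike-in factors varied within groups by an SD of 0.12 to 0.32 on the log2 scale. Under spike-in scaling 106 of 373 gene results and 20 of 128 list results lost their call.

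**Figure D1:**
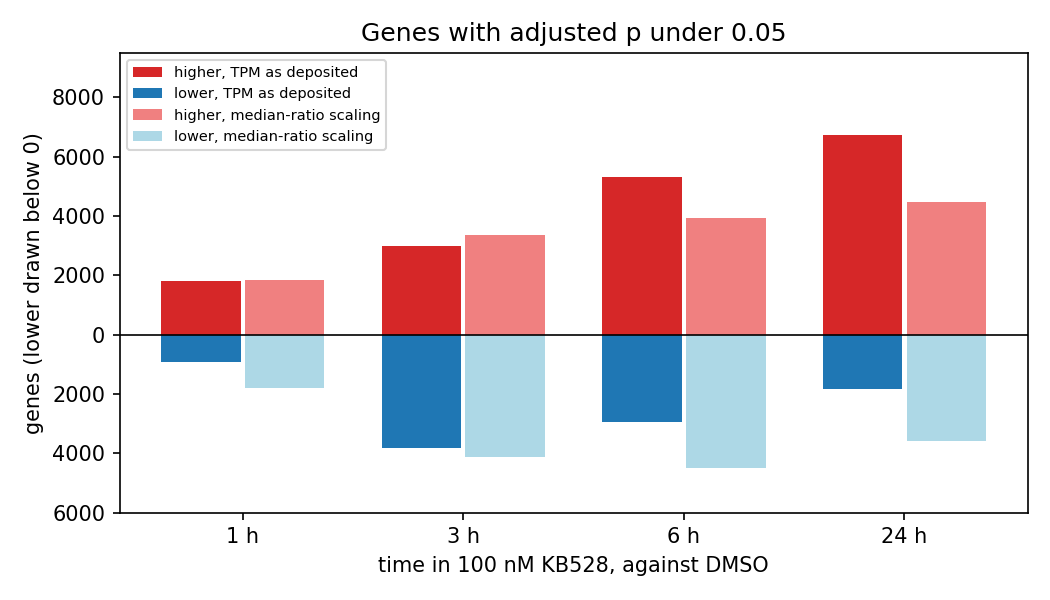
Number of genes called higher (up) and lower (down) than DMSO at each time in 100 nM KB528, by limma at an adjusted p under 0.05. Higher calls numbered 1802 at 1 h and 6738 at 24 h, and lower calls were most numerous at 3 h (3836); with median-ratio scaling they were most numerous at 6 h (4504) and after length correction at 24 h (3727).

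At 1 h RRAD, a small GTPase gene, had the largest increase among the named genes, from 0.335 ± 0.0990 to 25.6 ± 3.06 TPM (log2 fold change 4.31, SE 0.10, adjusted p = 8.17e-14). CDKN1A, which encodes the cyclin-dependent kinase inhibitor p21, rose from 18.4 ± 2.44 to 159 ± 3.56 TPM (log2 fold change 3.05, SE 0.077, adjusted p = 3.17e-13). MDM2, which encodes the ubiquitin ligase of p53, rose from 10.6 ± 0.873 to 65.1 ± 1.37 TPM. NFKBIA, which encodes an inhibitor of NF-kB, rose from 24.0 ± 1.51 to 191 ± 2.71 TPM. The transcription factor genes ATF3, FOSB and NR4A1 rose by 2.88, 2.80 and 2.50, and BBC3, a BH3-only cell death gene, by 2.05. TXNIP, which encodes thioredoxin-interacting protein, fell from 177 ± 9.84 to 34.9 ± 1.43 TPM (log2 fold change -2.31, SE 0.045, adjusted p = 1.55e-14). DDIT4, an inhibitor of mTOR signalling, fell by 1.65 and the phosphatase gene DUSP1 fell by 1.41 on the log2 scale. RAB3A (-1.45), ZNF217 (-1.21) and CISH (-1.20) fell as well, as did SERTAD3, from 7.93 ± 0.422 to 2.77 ± 0.503 TPM. MIR6510 (-2.32) was lower too, but reads of so short an RNA are uncertain in this assay.

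Of the regulators of plasma cell identity, MYC fell from 808 ± 71.5 to 660.4 ± 6.61 TPM (log2 fold change -0.29, SE 0.059, adjusted p = 0.00274) and MAF, the oncogene of t(14;16) myeloma, fell by 0.26. IRF4 was at 91.6 ± 10.5 TPM in DMSO and 106 ± 1.68 TPM at 1 h, with a log2 fold change of 0.21 and adjusted p = 0.0534. XBP1, a transcription factor of the secretory program, rose by 0.20, and CCND2, which encodes cyclin D2, by 0.33. HEXIM1, which encodes an inhibitor of the elongation kinase P-TEFb, rose from 16.9 ± 1.06 to 45.8 ± 8.31 TPM (log2 fold change 1.37, SE 0.10, adjusted p = 1.44e-07). EP300 rose by 0.46 (adjusted p = 0.0304) and CREBBP, which encodes the related acetyltransferase CBP, by 0.41 (adjusted p = 0.0416). PRDM1 (-0.18), IKZF1 (-0.025), IKZF3 (0.10), POU2AF1 (0.12), MEF2C (0.036), TNFRSF17 (0.18) and SDC1 (-0.021) did not pass the test.

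Gene lists were compared with the other genes tested, so that a list is called higher or lower relative to them, and 14 of 32 were called at 1 h, 9 higher and 5 lower. With median-ratio scaling there were 7 higher and 6 lower, and by fry, which sets a list against DMSO and not against other genes, 11 higher and 0 lower. Among 25 p53 targets, 20 rose and 2 fell (20 and 2 adjusted over the list alone). The median was 0.56 (camera adjusted p = 9.9e-14, or adjusted p = 0.465 with an estimated correlation). TNFRSF10B, a death receptor gene, rose by 1.86 and PHLDA3 by 1.91. 19 of 29 immediate early and CREB-linked genes rose and 7 fell (19 and 7 adjusted over the list alone). Their median was 0.53 (camera adjusted p = 0.000423, or adjusted p = 0.908 with an estimated correlation). FOSL1, JUND and JUNB, which encode AP-1 subunits, rose by 1.92, 1.20 and 1.09. For NF-kB targets, 14 of 24 rose and 0 fell (16 and 0 adjusted over the list alone). The median was 0.22 (camera adjusted p = 4.04e-06, or adjusted p = 0.908 with an estimated correlation). TNFAIP3 rose by 1.33. Of 31 genes of the ATF4 stress response, 15 rose and 2 fell (15 and 2 adjusted over the list alone). Their median was 0.13 (camera adjusted p = 0.00151, or adjusted p = 0.908 with an estimated correlation). SESN2 and DDIT3 rose by 0.91 and 0.91. Among 37 endoplasmic reticulum (ER) chaperone and secretion genes, 15 rose and 1 fell (19 and 1 adjusted over the list alone). The median was 0.14 (camera adjusted p = 0.000547, or adjusted p = 0.908 with an estimated correlation). DNAJB9 rose by 1.07.

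9 of 24 bromodomain and P-TEFb genes rose and 1 fell (11 and 1 adjusted over the list alone). Their median was 0.19 (camera adjusted p = 0.00109, or adjusted p = 0.908 with an estimated correlation). BRD2, which encodes a BET bromodomain protein, rose by 1.16. For polyadenylated histone transcripts, a family whose reads may be shared, 11 of 20 rose and 0 fell (12 and 1 adjusted over the list alone). The median was 0.27 (camera adjusted p = 0.000313, or adjusted p = 0.908 with an estimated correlation). Of 50 MYC targets and nucleolar protein genes, 18 rose and 0 fell (19 and 0 adjusted over the list alone). Their median was 0.11 (camera adjusted p = 0.0141, or adjusted p = 0.908 with an estimated correlation). Among 50 DNA replication and G1/S genes, 13 rose and 2 fell (15 and 2 adjusted over the list alone). The median was 0.080 (camera adjusted p = 0.0168, or adjusted p = 0.908 with an estimated correlation). 1 of 52 mitosis and G2/M genes rose and 15 fell (1 and 16 adjusted over the list alone). Their median was -0.086 (camera adjusted p = 3.34e-06, or adjusted p = 0.908 with an estimated correlation). For interferon-stimulated genes, 2 of 34 rose and 6 fell (2 and 6 adjusted over the list alone). The median was -0.069 (camera adjusted p = 0.00446, or adjusted p = 0.908 with an estimated correlation). Of 77 cytosolic ribosomal protein genes, 1 rose and 11 fell (0 and 0 adjusted over the list alone). Their median was -0.10 (camera adjusted p = 2.09e-09, or adjusted p = 0.908 with an estimated correlation). Among 57 nuclear genes of oxidative phosphorylation, 1 rose and 9 fell (0 and 0 adjusted over the list alone). The median was -0.10 (camera adjusted p = 4.27e-07, or adjusted p = 0.908 with an estimated correlation). 1 of 34 proteasome subunit genes rose and 1 fell (0 and 0 adjusted over the list alone). Their median was -0.063 (camera adjusted p = 0.011, or adjusted p = 0.908 with an estimated correlation). Transcripts of the ribosomal and oxidative phosphorylation lists are short, with medians of 1181 and 1256 bases. Both lists were still called lower at 1 h after length correction, but neither passed by fry (adjusted p = 0.201 and 0.158). Over protein-coding genes the median log2 fold change ran from -0.078 in the tenth with the shortest transcripts to 0.13 in the tenth with the longest.

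Several 1 h calls rested on single choices. The EP300 call was lost without DMSO replicate 1 (0.45), DMSO replicate 2 (0.30), KB528 replicate 1 (0.45), KB528 replicate 2 (0.46) or KB528 replicate 3 (0.47), and the CREBBP call without DMSO replicate 1 (0.39), DMSO replicate 2 (0.28), KB528 replicate 1 (0.40), KB528 replicate 2 (0.39) or KB528 replicate 3 (0.43). MAF missed without DMSO replicate 1 (-0.26), DMSO replicate 3 (-0.20) or KB528 replicate 3 (-0.16), with only the compared groups in the fit and without a variance trend, which also ended the CREBBP call. IRF4 passed without DMSO replicate 3 (0.30), POU2AF1 without DMSO replicate 3 (0.21) and TNFRSF17 without DMSO replicate 1 (0.22). Proteasome subunits at 1 h were not called without DMSO replicate 1 (0.0859) or DMSO replicate 2 (0.0609) or after length correction (adjusted p between 0.000569 and 0.908 over all alternatives), nor MYC targets and DNA replication genes with median-ratio scaling. Heat shock at 1 h, not called, passed without DMSO replicate 2 (0.0122) or KB528 replicate 1 (0.0494), with median-ratio scaling, length correction, a pseudocount of 0.1 and no filter (adjusted p between 0.00916 and 0.908 over all alternatives). After length correction IRF4 (0.12), PRDM1 (-0.27), IKZF1 (-0.13) and TNFRSF17 (0.22) also passed. IRF4 and PRDM1 passed with median-ratio scaling too, and IRF4 and TNFRSF17 at a filter of 5 TPM, with the spike-ins out of the total and without small RNA genes. Without a filter EP300, CREBBP and MAF missed. Spike-in scaling ended the calls of MYC, XBP1, MAF, CCND2, EP300, CREBBP and the MYC target, ER, DNA replication and proteasome lists.

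At 3 h MYC fell from 808 ± 71.5 to 267 ± 14.6 TPM (log2 fold change -1.59, SE 0.059, adjusted p = 1.64e-11). MAF fell from 403 ± 39.0 to 185 ± 17.2 TPM, and IKZF1, which encodes Ikaros, from 29.1 ± 3.95 to 13.2 ± 1.35 TPM. MEF2C fell from 27.8 ± 2.86 to 13.7 ± 0.569 TPM, POU2AF1, a B cell coactivator gene, from 110.4 ± 14.3 to 59.3 ± 5.45 TPM, and PRDM1, which encodes BLIMP-1, from 26.7 ± 5.01 to 14.4 ± 1.60 TPM. IKZF3, which encodes Aiolos, fell by 0.25 and SDC1, the plasma cell surface marker CD138, fell by 0.70. IRF4 itself was at 85.8 ± 6.90 TPM, with a log2 fold change of -0.091 and adjusted p = 0.316. XBP1, CCND2 and TNFRSF17, which encodes the surface receptor BCMA, rose by 0.35, 0.30 and 0.15. HEXIM1 rose from 16.9 ± 1.06 to 83.1 ± 6.54 TPM (log2 fold change 2.23, SE 0.10, adjusted p = 1.23e-10), EP300 by 0.40 and CREBBP by 0.48.

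RRAD had the largest increase among genes ranked under the naming rule, from 0.335 ± 0.0990 to 24.7 ± 0.507 TPM (log2 fold change 4.27, SE 0.10, adjusted p = 1.26e-13). The long non-coding MIR663AHG (3.04) and FAM222A (2.30) followed. SKIL, a repressor of SMAD signalling, rose by 1.91 and RELB, an NF-kB subunit gene, by 1.85. SNORD49A (1.96) and HIST1H4C (1.91) also rose, and both belong to families whose reads are uncertain in this assay. FOS, which encodes an AP-1 subunit, fell from 43.1 ± 11.1 to 5.58 ± 0.301 TPM (log2 fold change -2.72, SE 0.13, adjusted p = 1.82e-10), and the somatostatin receptor gene SSTR3 from 45.9 ± 3.04 to 6.14 ± 0.119 TPM. CITED2, which encodes a protein that binds p300 and CBP, fell from 221 ± 20.1 to 37.7 ± 1.91 TPM (log2 fold change -2.51, SE 0.056, adjusted p = 9.82e-14). SH2D3C (-2.66), DUSP5 (-2.39), C1orf106 (-2.31) and TMCC2 (-2.29) fell as well, as did PRAMEF4 (-2.28), of a multi-copy family.

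At this time 15 of 32 lists were called, 7 higher and 8 lower (8 higher and 14 lower by fry). For plasma cell transcription factor genes, 1 of 19 rose and 15 fell (1 and 15 adjusted over the list alone). The median was -0.83 (camera adjusted p = 2.25e-05, or adjusted p = 0.657 with an estimated correlation). KLF2 fell by 2.14 and IRF1 fell by 1.42. Of 8 genes of the t(14;16) MAF program, 1 rose and 7 fell (1 and 7 adjusted over the list alone). Their median was -0.95 (camera adjusted p = 0.00055, or adjusted p = 0.657 with an estimated correlation). CCR1, a chemokine receptor gene, fell by 1.32. Among 21 B cell identity genes, 2 rose and 17 fell (3 and 17 adjusted over the list alone). The median was -0.40 (camera adjusted p = 0.000571, or adjusted p = 0.657 with an estimated correlation). CD72 fell by 1.27. 4 of 21 myeloma surface antigen genes rose and 12 fell (4 and 12 adjusted over the list alone). Their median was -0.26 (camera adjusted p = 0.0282, or adjusted p = 0.667 with an estimated correlation). CXCR4 fell by 0.92. For interferon-stimulated genes, 1 of 34 rose and 23 fell (2 and 23 adjusted over the list alone). The median was -0.26 (camera adjusted p = 0.000225, or adjusted p = 0.657 with an estimated correlation). OAS1 fell by 1.33. Of 22 heat shock genes, 1 rose and 14 fell (1 and 14 adjusted over the list alone). Their median was -0.20 (camera adjusted p = 0.00342, or adjusted p = 0.657 with an estimated correlation). Among 52 mitosis and G2/M genes, 2 rose and 31 fell (3 and 33 adjusted over the list alone). The median was -0.18 (camera adjusted p = 0.00204, or adjusted p = 0.727 with an estimated correlation). BUB1 fell by 0.62. 0 of 9 epithelial markers rose and 6 fell (0 and 6 adjusted over the list alone). Their median was -0.25 (camera adjusted p = 0.0202, or adjusted p = 0.657 with an estimated correlation). These are the members of a list of 16 that passed the filter in this line, and CLDN4 fell by 1.51.

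For MYC targets and nucleolar protein genes, 27 of 50 rose and 2 fell (27 and 2 adjusted over the list alone). The median was 0.18 (camera adjusted p = 2.25e-05, or adjusted p = 0.657 with an estimated correlation). NOP56 rose by 0.55, while MYC itself fell. Of 50 DNA replication and G1/S genes, 28 rose and 8 fell (29 and 8 adjusted over the list alone). Their median was 0.15 (camera adjusted p = 2.25e-05, or adjusted p = 0.657 with an estimated correlation). RRM2, a ribonucleotide reductase gene, rose from 141 ± 13.9 to 295 ± 6.91 TPM. Among 37 ER chaperone and secretion genes, 19 rose and 6 fell (19 and 6 adjusted over the list alone). The median was 0.13 (camera adjusted p = 0.00518, or adjusted p = 0.667 with an estimated correlation). HSPA5, which encodes BiP, rose by 0.58. 12 of 24 NF-kB targets rose and 6 fell (12 and 6 adjusted over the list alone). Their median was 0.28 (camera adjusted p = 0.00381, or adjusted p = 0.657 with an estimated correlation). CD83 rose by 1.37. For p53 targets, 18 of 25 rose and 4 fell (18 and 4 adjusted over the list alone). The median was 0.36 (camera adjusted p = 0.000292, or adjusted p = 0.657 with an estimated correlation). CDKN1A rose by 1.54 and TIGAR by 1.33. Of 24 bromodomain and P-TEFb genes, 13 rose and 4 fell (13 and 4 adjusted over the list alone). Their median was 0.20 (camera adjusted p = 0.00445, or adjusted p = 0.667 with an estimated correlation). Among 20 polyadenylated histone transcripts, 12 rose and 3 fell (13 and 3 adjusted over the list alone). The median was 0.41 (camera adjusted p = 0.0016, or adjusted p = 0.657 with an estimated correlation). The IRF4 target list, assembled from memory of the literature, was not called at 3 h. It gave 4 that rose and 12 that fell of 22 (4 and 12 adjusted over the list alone), a median of -0.20 and a camera adjusted p = 0.0913.

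The EP300 call at 3 h was lost without DMSO replicate 1 (0.40), DMSO replicate 2 (0.25), KB528 replicate 1 (0.39) or KB528 replicate 3 (0.26), the IKZF3 call without DMSO replicate 3 (-0.17) or KB528 replicate 2 (-0.20) and the TNFRSF17 call without DMSO replicate 2 (0.15), DMSO replicate 3 (0.11) or KB528 replicate 2 (0.071). EP300, IKZF3 and TNFRSF17 also missed with only the compared groups in the fit, EP300 and TNFRSF17 without a filter, and TNFRSF17 with median-ratio scaling. Its sign changed with spike-in scaling (-0.068), which ended the calls of XBP1, IKZF3, CCND2, EP300, CREBBP and the ER, surface antigen and heat shock lists and brought the IRF4 target and immediate early lists past the threshold. The epithelial call was lost at a filter of 5 TPM. Cytosolic ribosomal proteins at 3 h, with a median of -0.084, passed without DMSO replicate 3 (0.000109) or KB528 replicate 2 (5.74e-05) (adjusted p between 5.74e-05 and 0.925 over all alternatives). Oxidative phosphorylation (nuclear) at 3 h (-0.079) passed without DMSO replicate 3 (0.00279) or KB528 replicate 2 (0.00147) (adjusted p between 0.00147 and 0.925 over all alternatives). Both lists also passed without a filter, as did the IRF4 target list (adjusted p = 0.0178), which passed by fry as well (adjusted p = 0.000202, between 0.000202 and 0.806 over all alternatives).

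At 6 h IRF4 was lower. It fell from 91.6 ± 10.5 to 39.2 ± 2.90 TPM (log2 fold change -1.20, SE 0.075, adjusted p = 3.08e-09), and MYC fell from 808 ± 71.5 to 235 ± 14.5 TPM (log2 fold change -1.77, SE 0.059, adjusted p = 3.7e-12). POU2AF1 fell from 110.4 ± 14.3 to 38.6 ± 2.73 TPM, and MAF from 403 ± 39.0 to 179 ± 12.2 TPM. SDC1 fell by 1.30 on the log2 scale. TNFRSF17 fell by 0.73 to 73.9 ± 0.564 TPM, MEF2C fell by 0.40 and IKZF3 fell by 0.36. EP300 rose from 22.1 ± 4.97 to 48.4 ± 4.73 TPM (log2 fold change 1.12, SE 0.14, adjusted p = 4.86e-06) and CREBBP from 16.6 ± 3.40 to 41.8 ± 3.03 TPM (log2 fold change 1.30, SE 0.13, adjusted p = 6.5e-07). HEXIM1 rose from 16.9 ± 1.06 to 59.3 ± 1.60 TPM. PRDM1 (0.082), XBP1 (-0.019), IKZF1 (-0.12) and CCND2 (0.035) did not pass the test.

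Of the genes ranked under the naming rule, SKIL had the largest increase at 6 h on the log2(TPM + 1) scale. It rose from 3.53 ± 0.407 to 20.3 ± 0.802 TPM (log2 fold change 2.24, SE 0.075, adjusted p = 3.7e-12). HMOX1, which encodes heme oxygenase 1, rose from 151 ± 9.08 to 473 ± 23.9 TPM, and the chemokine gene CXCL10 by 1.80. FAM222A (1.73), RRAD (1.62) and MIR663AHG (1.57) were still higher than in DMSO, as was SNORD49A, at 36.3 ± 7.03 TPM, whose reads are uncertain. FOS fell from 43.1 ± 11.1 to 2.07 ± 0.309 TPM (log2 fold change -3.82, SE 0.13, adjusted p = 4.02e-12). P2RX7, an ATP-gated channel gene, fell from 29.8 ± 4.39 to 2.47 ± 0.307 TPM, and the endothelin gene EDN2 from 12.7 ± 0.273 to 0.654 ± 0.0482 TPM. IGFBP3, which encodes an insulin-like growth factor binding protein, fell from 677 ± 25.1 to 105 ± 4.74 TPM (log2 fold change -2.68, SE 0.042, adjusted p = 1.32e-15). AFAP1L2 (-2.67), TFAP2C (-2.53), OAS1 (-2.52) and SSTR3 (-2.51) fell as well.

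Of the 32 lists 21 were called at 6 h, 7 higher and 14 lower. 44 of 52 mitosis and G2/M genes rose and 2 fell (45 and 2 adjusted over the list alone). Their median was 0.67 (camera adjusted p = 3.36e-09, or adjusted p = 0.504 with an estimated correlation). KIF2C and AURKA, which encode mitotic spindle regulators, rose by 0.93 and 0.82. For DNA replication and G1/S genes, 40 of 50 rose and 1 fell (40 and 1 adjusted over the list alone). The median was 0.42 (camera adjusted p = 4.02e-07, or adjusted p = 0.6 with an estimated correlation). RRM2 rose by 1.15. Of 22 heat shock genes, 15 rose and 2 fell (16 and 2 adjusted over the list alone). Their median was 0.38 (camera adjusted p = 0.00554, or adjusted p = 0.663 with an estimated correlation). DNAJB1 rose by 1.36 and HSPA8 by 0.63. Among 24 NF-kB targets, 19 rose and 4 fell (19 and 4 adjusted over the list alone). The median was 0.38 (camera adjusted p = 0.0188, or adjusted p = 0.663 with an estimated correlation). 17 of 24 bromodomain and P-TEFb genes, with a median transcript of 4815 bases, rose and 1 fell (17 and 1 adjusted over the list alone). Their median was 0.38 (camera adjusted p = 0.00946, or adjusted p = 0.663 with an estimated correlation). For proteasome subunit genes, 22 of 34 rose and 1 fell (22 and 1 adjusted over the list alone). The median was 0.21 (camera adjusted p = 0.0139, or adjusted p = 0.663 with an estimated correlation). Of 43 autophagy and lysosome genes, 25 rose and 7 fell (27 and 7 adjusted over the list alone). Their median was 0.18 (camera adjusted p = 0.0406, or adjusted p = 0.747 with an estimated correlation). SQSTM1, an autophagy receptor gene, rose from 243 ± 7.50 to 638 ± 29.6 TPM.

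Among 19 plasma cell transcription factor genes, 1 rose and 14 fell (1 and 14 adjusted over the list alone). The median was -0.49 (camera adjusted p = 4.02e-07, or adjusted p = 0.5 with an estimated correlation). KLF2 fell by 2.36. 8 of 22 IRF4 targets rose and 11 fell (8 and 11 adjusted over the list alone). Their median was -0.13 (camera adjusted p = 0.0188, or adjusted p = 0.663 with an estimated correlation). The fallen members included MYC, KLF2 and SCD (-0.54), a fatty acid desaturase gene. For genes of the MAF program, 0 of 8 rose and 7 fell (0 and 7 adjusted over the list alone). The median was -0.59 (camera adjusted p = 4.84e-05, or adjusted p = 0.438 with an estimated correlation). DEPTOR, an mTOR-binding protein gene, fell from 182 ± 11.9 to 34.7 ± 1.14 TPM. Of 21 B cell identity genes, 3 rose and 16 fell (3 and 16 adjusted over the list alone). Their median was -0.60 (camera adjusted p = 3.41e-07, or adjusted p = 0.337 with an estimated correlation). SPI1, which encodes PU.1, fell by 1.08. Among 21 myeloma surface antigen genes, 4 rose and 15 fell (4 and 15 adjusted over the list alone). The median was -0.39 (camera adjusted p = 4.34e-05, or adjusted p = 0.438 with an estimated correlation). IL6R, the interleukin 6 receptor gene, fell by 1.37. 4 of 34 interferon-stimulated genes rose and 19 fell (4 and 19 adjusted over the list alone). Their median was -0.27 (camera adjusted p = 2.43e-05, or adjusted p = 0.329 with an estimated correlation). For immediate early genes, 6 of 29 rose and 16 fell (8 and 16 adjusted over the list alone). The median was -0.23 (camera adjusted p = 0.0016, or adjusted p = 0.663 with an estimated correlation). JUN fell by 1.46. Of 31 genes of the ATF4 response, 6 rose and 15 fell (6 and 15 adjusted over the list alone). Their median was -0.14 (camera adjusted p = 0.00909, or adjusted p = 0.663 with an estimated correlation). Among 23 cholesterol synthesis genes, 5 rose and 15 fell (5 and 15 adjusted over the list alone). The median was -0.21 (camera adjusted p = 0.00606, or adjusted p = 0.663 with an estimated correlation). MSMO1 fell by 0.91. 9 of 25 HIF targets rose and 13 fell (9 and 13 adjusted over the list alone). Their median was -0.21 (camera adjusted p = 0.0388, or adjusted p = 0.675 with an estimated correlation).

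Among 5 lists of markers of other cells, those of T cells and epithelium had enough tested members for a comparison, and both were called lower at 6 h. For T cell markers, 0 of 6 rose and 6 fell (0 and 6 adjusted over the list alone). The median was -0.36 (camera adjusted p = 0.00909, or adjusted p = 0.232 with an estimated correlation). They are the tested members among 17 found in the table. CD8B was at 416 ± 12.2 TPM against 490.1 ± 13.8 TPM in DMSO. Of 9 epithelial markers, 0 rose and 8 fell (0 and 8 adjusted over the list alone). Their median was -0.43 (camera adjusted p = 0.00025, or adjusted p = 0.125 with an estimated correlation). ESRP1 fell by 0.98. Among 77 cytosolic ribosomal protein genes, 0 rose and 18 fell (0 and 1 adjusted over the list alone). The median was -0.086 (camera adjusted p = 0.000232, or adjusted p = 0.741 with an estimated correlation). 9 of 57 nuclear genes of oxidative phosphorylation rose and 10 fell (4 and 4 adjusted over the list alone). Their median was -0.049 (camera adjusted p = 0.0406, or adjusted p = 0.783 with an estimated correlation). The median log2 fold change of protein-coding genes was -0.031 in the tenth with the shortest transcripts and 0.20 in the tenth with the longest.

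PRDM1 passed at 6 h without DMSO replicate 3 (0.22) and IKZF1 without DMSO replicate 2 (-0.22). With median-ratio scaling XBP1 (-0.18) and IKZF1 (-0.27) passed as lower, IKZF1 also after length correction, and CCND2 passed as lower under both (-0.12 and -0.10). The call of Oxidative phosphorylation (nuclear) at 6 h was lost without DMSO replicate 1 (0.143), DMSO replicate 2 (0.197), KB528 replicate 1 (0.0606) or KB528 replicate 3 (0.0729), without a filter and after length correction (adjusted p between 0.000828 and 0.783 over all alternatives). That of Autophagy and lysosome at 6 h was lost without DMSO replicate 1 (0.0745), KB528 replicate 2 (0.053) or KB528 replicate 3 (0.0524), at a filter of 5 TPM, with only the compared groups in the fit, with median-ratio scaling and after length correction (adjusted p between 0.000131 and 0.747 over all alternatives). Proteasome subunits at 6 h missed without DMSO replicate 3 (0.0691) and with median-ratio scaling (adjusted p between 9.31e-05 and 0.663 over all alternatives), the HIF list with median-ratio scaling and the ribosomal list after length correction. Spike-in scaling ended the calls of IKZF3, MEF2C, SCD, CD8B and the ribosomal, cholesterol, proteasome, HIF, oxidative phosphorylation and autophagy lists. In the p53, glycolysis and housekeeping lists, which were not called, the median was above 0 and the test pointed down.

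**Figure D2:**
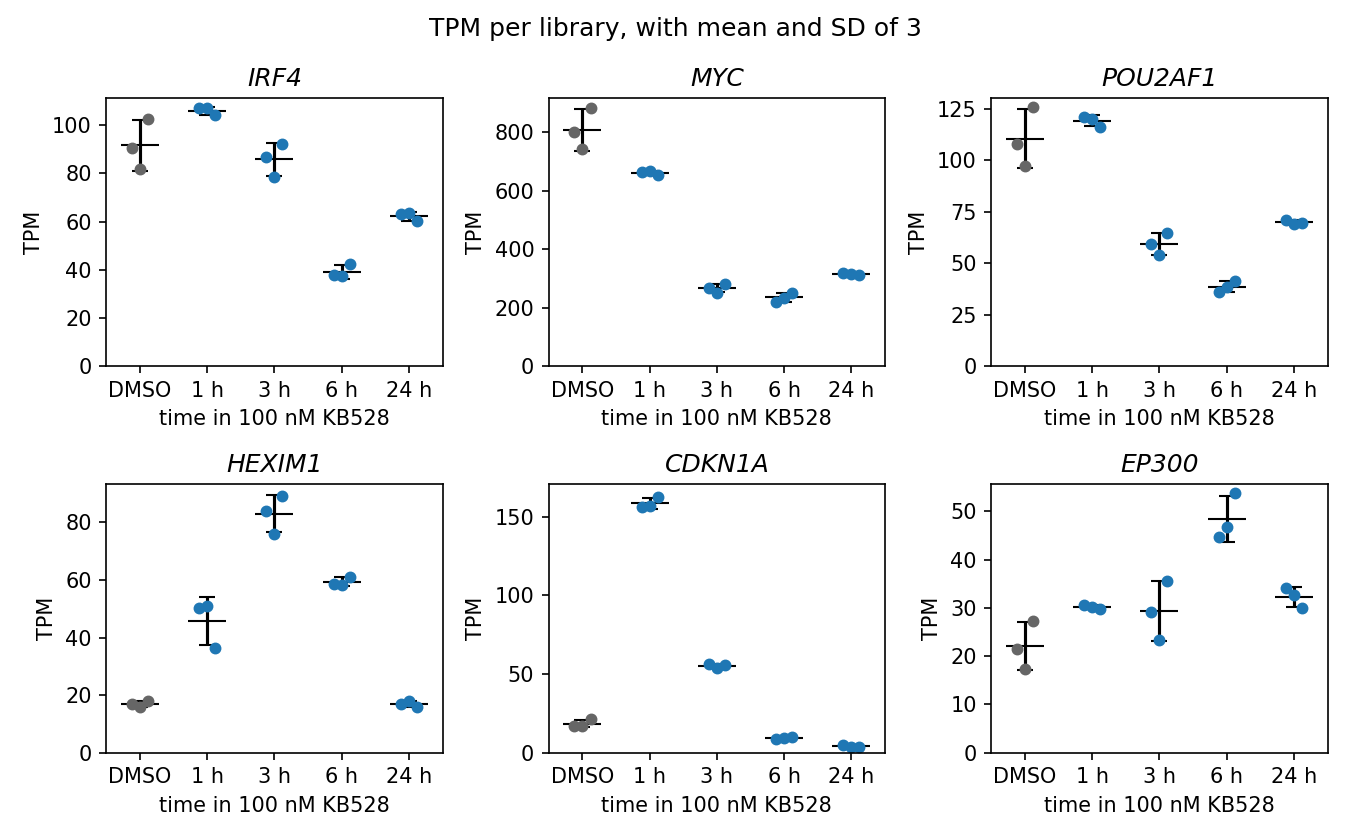
TPM of IRF4, MYC, POU2AF1, HEXIM1, CDKN1A and EP300 in each library (points) with the mean and SD of 3 libraries (bars), in DMSO and after 1, 3, 6 and 24 h in 100 nM KB528. IRF4 was lowest at 6 h (39.2 ± 2.90 TPM), CDKN1A highest at 1 h (159 ± 3.56 TPM) and EP300 highest at 6 h (48.4 ± 4.73 TPM).

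At 24 h MYC and IRF4 were still below DMSO. MYC fell from 808 ± 71.5 to 315 ± 4.09 TPM (log2 fold change -1.35, SE 0.059, adjusted p = 1.06e-10) and IRF4 from 91.6 ± 10.5 to 62.2 ± 1.88 TPM (log2 fold change -0.55, SE 0.075, adjusted p = 1.33e-05). TNFRSF17 fell by 1.28 on the log2 scale (SE 0.062, adjusted p = 3.15e-10). PRDM1 (-0.27), XBP1 (-0.45), POU2AF1 (-0.64), MAF (-0.51), CCND2 (-0.31) and SDC1 (-0.62) fell as well, while EP300 rose by 0.55, CREBBP by 0.70 and IKZF1 by 0.23. HEXIM1 (adjusted p = 0.968) did not pass, nor did IKZF3 (0.15) or MEF2C (-0.016).

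LTF, which encodes lactoferrin, had the largest increase at 24 h among genes ranked under the naming rule. It rose from 8.12 ± 0.509 to 66.9 ± 1.20 TPM (log2 fold change 2.90, SE 0.064, adjusted p = 7.04e-14). CXCL10 rose from 4.39 ± 0.890 to 29.9 ± 1.95 TPM and HMOX1 from 151 ± 9.08 to 569 ± 11.1 TPM (log2 fold change 1.91, SE 0.047, adjusted p = 1.84e-13). AKR1C1, an aldo-keto reductase gene with close paralogs, rose by 1.95. PEX5L (1.84), ABTB1 (1.69), PKN3 (1.62) and COL9A2 (1.60) rose as well. FOS fell from 43.1 ± 11.1 to 1.00 ± 0.155 TPM (log2 fold change -4.44, SE 0.13, adjusted p = 1.78e-12) and DUSP1 from 84.9 ± 22.7 to 9.98 ± 0.607 TPM. EDN2 fell by 3.18, KRT6C, a keratin gene with near-identical copies, fell from 31.4 ± 2.47 to 2.81 ± 0.377 TPM and KRT15 from 258 ± 3.50 to 48.2 ± 1.01 TPM. MT1A, of the multi-copy metallothionein family, fell by 2.54. The exonuclease gene ISG20 fell by 2.02, and BHLHA15, which encodes the secretory cell factor MIST1, fell from 160.4 ± 9.25 to 40.5 ± 1.67 TPM (log2 fold change -1.96, SE 0.086, adjusted p = 1.06e-10).

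Of the 32 lists 22 were called at 24 h, 4 higher and 18 lower. Fry gave 12 higher and 12 lower, and spike-in scaling 1 higher and 14 lower. For ER chaperone and secretion genes, 2 of 37 rose and 31 fell (2 and 31 adjusted over the list alone). The median was -0.49 (camera adjusted p = 7.04e-23, or adjusted p = 0.113 with an estimated correlation). MZB1, a plasma cell ER cochaperone gene, fell from 2618 ± 87.7 to 1172 ± 10.0 TPM and HSPA5 from 710.3 ± 42.7 to 403 ± 5.05 TPM. Of 23 cholesterol synthesis genes, 1 rose and 20 fell (1 and 21 adjusted over the list alone). Their median was -0.63 (camera adjusted p = 2.81e-19, or adjusted p = 0.113 with an estimated correlation). INSIG1, a regulator of sterol sensing, fell from 196 ± 15.6 to 56.1 ± 1.08 TPM, and HMGCS1 fell by 1.15. Among 50 MYC targets and nucleolar protein genes, called higher at 1 h and 3 h, 0 rose and 38 fell (0 and 38 adjusted over the list alone). The median was -0.27 (camera adjusted p = 8.11e-20, or adjusted p = 0.134 with an estimated correlation). NOP16 fell by 0.88 and ODC1, which encodes ornithine decarboxylase, fell by 0.91. 5 of 22 IRF4 targets rose and 15 fell (5 and 15 adjusted over the list alone). Their median was -0.39 (camera adjusted p = 7.77e-09, or adjusted p = 0.196 with an estimated correlation). FKBP11 fell by 0.77. For plasma cell transcription factor genes, 2 of 19 rose and 11 fell (2 and 11 adjusted over the list alone). The median was -0.27 (camera adjusted p = 8.77e-07, or adjusted p = 0.366 with an estimated correlation). Of 8 genes of the MAF program, 1 rose and 6 fell (1 and 6 adjusted over the list alone). Their median was -0.59 (camera adjusted p = 9.48e-06, or adjusted p = 0.24 with an estimated correlation). ITGB7, an integrin gene, fell from 2538 ± 120.0 to 1156 ± 22.6 TPM. Among 21 myeloma surface antigen genes, 5 rose and 13 fell (5 and 13 adjusted over the list alone). The median was -0.50 (camera adjusted p = 1.97e-07, or adjusted p = 0.161 with an estimated correlation). CD38 fell by 0.89. 6 of 21 B cell identity genes rose and 10 fell (6 and 10 adjusted over the list alone). Their median was -0.057 (camera adjusted p = 0.000108, or adjusted p = 0.366 with an estimated correlation). For immediate early genes, 5 of 29 rose and 17 fell (6 and 17 adjusted over the list alone). The median was -0.31 (camera adjusted p = 1.49e-08, or adjusted p = 0.419 with an estimated correlation).

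Of 52 mitosis and G2/M genes, 47 rose and 1 fell (47 and 1 adjusted over the list alone). Their median was 0.52 (camera adjusted p = 8.77e-07, or adjusted p = 0.506 with an estimated correlation). NUSAP1 rose by 0.75. Among 43 autophagy and lysosome genes, 33 rose and 2 fell (33 and 2 adjusted over the list alone). The median was 0.32 (camera adjusted p = 0.0196, or adjusted p = 0.683 with an estimated correlation). GABARAP rose by 0.54. 25 of 29 histone acetyltransferase and deacetylase genes, with a median transcript of 4196 bases, rose and 1 fell (25 and 1 adjusted over the list alone). Their median was 0.39 (camera adjusted p = 0.0233, or adjusted p = 0.683 with an estimated correlation). HDAC1 rose by 0.45. For DNA replication and G1/S genes, 37 of 50 rose and 3 fell (38 and 3 adjusted over the list alone). The median was 0.29 (camera adjusted p = 0.0196, or adjusted p = 0.686 with an estimated correlation). TYMS, which encodes thymidylate synthase, rose by 0.59. The median log2 fold change of protein-coding genes was 0.044 in the tenth with the shortest transcripts and 0.31 in the tenth with the longest.

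Other lists called lower at 24 h had medians between -0.22 and -0.0038, below the all-gene median of 0.23. Of 23 glycolysis genes, 3 rose and 9 fell (3 and 9 adjusted over the list alone). Their median was -0.056 (camera adjusted p = 0.00165, or adjusted p = 0.506 with an estimated correlation). LDHA fell by 0.39. Among 25 HIF targets, 7 rose and 10 fell (7 and 10 adjusted over the list alone). The median was -0.058 (camera adjusted p = 0.00424, or adjusted p = 0.611 with an estimated correlation). 7 of 34 proteasome subunit genes rose and 4 fell (3 and 3 adjusted over the list alone). Their median was -0.0038 (camera adjusted p = 0.00884, or adjusted p = 0.664 with an estimated correlation). For nuclear genes of oxidative phosphorylation, 7 of 57 rose and 13 fell (7 and 11 adjusted over the list alone). The median was -0.015 (camera adjusted p = 0.000693, or adjusted p = 0.664 with an estimated correlation). Of 77 cytosolic ribosomal protein genes, 0 rose and 23 fell (0 and 16 adjusted over the list alone). Their median was -0.078 (camera adjusted p = 1.72e-09, or adjusted p = 0.611 with an estimated correlation). Among 31 genes of the ATF4 response, 8 rose and 9 fell (8 and 9 adjusted over the list alone). The median was -0.048 (camera adjusted p = 0.00772, or adjusted p = 0.664 with an estimated correlation). The mean of this list was 0.0084, of the opposite sign to its median. 3 of 20 replication-dependent histone transcripts, uncertain in polyadenylated RNA, rose and 7 fell (3 and 6 adjusted over the list alone). Their median was -0.22 (camera adjusted p = 0.0043, or adjusted p = 0.132 with an estimated correlation). For T cell markers, 1 of 6 rose and 3 fell (1 and 3 adjusted over the list alone). The median was -0.15 (camera adjusted p = 0.0172, or adjusted p = 0.134 with an estimated correlation). Of 9 epithelial markers, 1 rose and 5 fell (1 and 5 adjusted over the list alone). Their median was -0.20 (camera adjusted p = 0.00656, or adjusted p = 0.134 with an estimated correlation).

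NF-kB targets, not called at 24 h, gave 17 that rose and 2 that fell of 24 (17 and 2 adjusted over the list alone), a median of 0.37 and a camera adjusted p = 0.142. Bromodomain and P-TEFb genes, called higher at 1 h, 3 h and 6 h, gave 15 that rose and 2 that fell of 24 (15 and 2 adjusted over the list alone), a median of 0.23 and a camera adjusted p = 0.443. Polyadenylated histone transcripts, called higher at 1 h and 3 h, gave 8 that rose and 5 that fell of 20 (8 and 5 adjusted over the list alone), a median of -0.0090 and a camera adjusted p = 0.126. Interferon-stimulated genes gave 20 that rose and 7 that fell of 34 (20 and 8 adjusted over the list alone), a median of 0.28 and a camera adjusted p = 0.898. MHC class I genes gave 11 that rose and 2 that fell of 16 (11 and 3 adjusted over the list alone), a median of 0.32 and a camera adjusted p = 0.443. MHC class II genes gave 4 that rose and 0 that fell of 5 (4 and 0 adjusted over the list alone), a median of 0.43 and a camera adjusted p = 0.32. The p53 targets gave 13 that rose and 5 that fell of 25 (14 and 5 adjusted over the list alone), a median of 0.19 and a camera adjusted p = 0.59. BCL2 family genes gave 9 that rose and 4 that fell of 16 (9 and 4 adjusted over the list alone), a median of 0.15 and a camera adjusted p = 0.419. Heat shock genes gave 11 that rose and 3 that fell of 22 (11 and 3 adjusted over the list alone), a median of 0.12 and a camera adjusted p = 0.59. Housekeeping genes gave 8 that rose and 5 that fell of 19 (8 and 5 adjusted over the list alone), a median of 0.051 and a camera adjusted p = 0.338. In the p53, BCL2, heat shock and housekeeping lists the median was above 0 and the test against the other genes pointed down. Lists with fewer than 5 tested members were not compared. Of these, 4 of 6 immunoglobulin genes found by name (20 were listed), 3 of 20 monocyte markers, 3 of 16 fibroblast and stromal markers and 3 of 13 erythroid markers passed the filter. The list of 15 mitochondrially encoded transcripts was not analysed here, since 0 were found by name.

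The PRDM1 call at 24 h was lost without DMSO replicate 3 (-0.13), KB528 replicate 2 (-0.27) or KB528 replicate 3 (-0.25), the IKZF1 call without DMSO replicate 2 (0.13) or KB528 replicate 1 (0.21), and both without a filter. IKZF3 passed as higher without DMSO replicate 3 (0.23), and as lower after length correction (-0.13), which turned IKZF1 negative as well (-0.025, not past the threshold). MEF2C passed as lower with median-ratio scaling (-0.21) and length correction (-0.28), and IKZF1 missed with median-ratio scaling. Median-ratio scaling ended the calls of the replication, autophagy, replication-dependent histone and T cell lists, length correction those of the replication, replication-dependent histone and T cell lists, and a filter of 5 TPM that of the histone list. Spike-in scaling ended the calls of PRDM1, XBP1, IKZF1, CCND2, LDHA and HDAC1 and of the ATF4, replication, acetyltransferase, glycolysis, autophagy, T cell and epithelial lists.

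**Figure D3:**
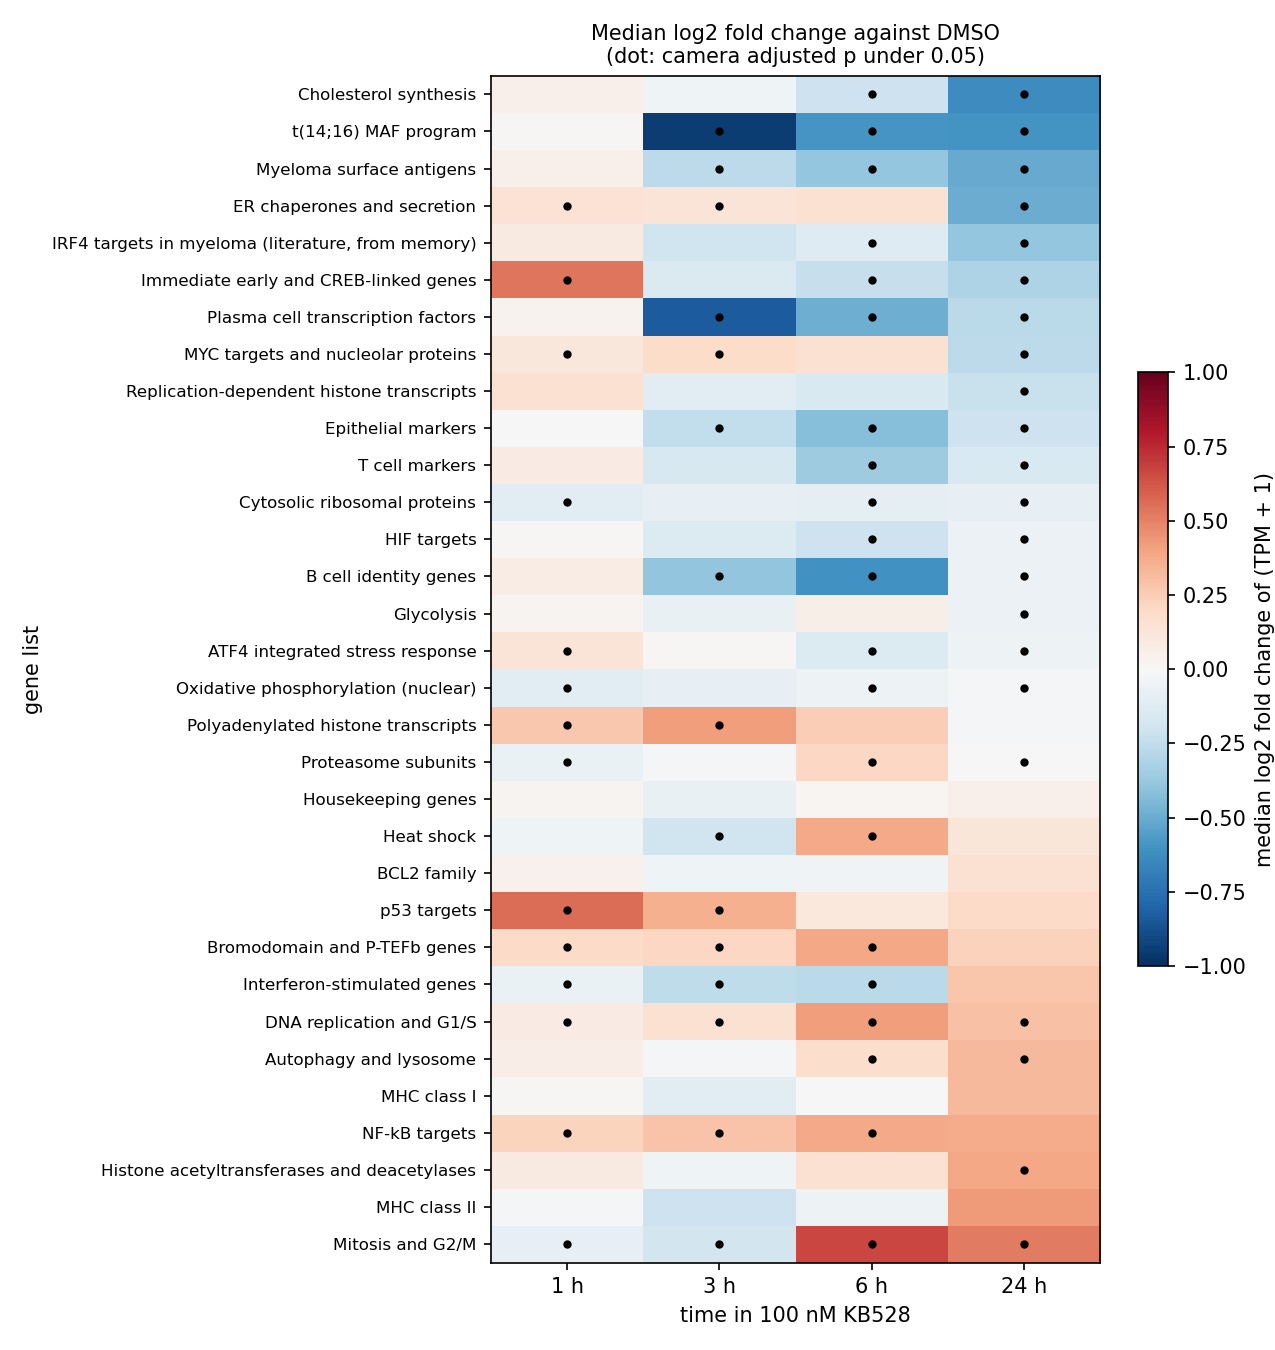
Median log2 fold change against DMSO, on the log2(TPM + 1) scale, of the measured members of each of 32 gene lists at 1, 3, 6 and 24 h in 100 nM KB528; a dot marks a camera adjusted p under 0.05 with the preset correlation. The p53 list was highest at 1 h (0.56) and the mitosis list at 6 h (0.67), and the ER list had a median of 0.14 at 1 h and -0.49 at 24 h.

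Between consecutive times, 5645 genes changed from 1 h to 3 h (1829 higher and 3816 lower), 6722 from 3 h to 6 h (5074 higher and 1648 lower) and 8047 from 6 h to 24 h (4925 higher and 3122 lower). Of the 3836 genes lower at 3 h, 2321 were lower at 6 h, and at 24 h 871 were lower, 1923 higher and 1042 not called. A smaller share of all 12002 genes was lower (1826) and a larger share higher (6738) at 24 h. Of the 2945 lower at 6 h, 1035 were lower and 966 higher at 24 h. Of the 5327 higher at 6 h, 3824 were higher and 316 lower at 24 h. The directions at 24 h and between times depended on the scaling. Median-ratio scaling gave 2939 higher and 3560 lower from 1 h to 3 h and 3103 and 3600 from 3 h to 6 h. After length correction the 3 steps in order gave 3990 higher and 3049 lower, 3523 and 3299, and 4078 and 4946. Scaling to the spike-ins gave 81 and 2070, 7362 and 232, and 1640 and 2037. Rescaling without them gave 4165 and 2229 from 3 h to 6 h.

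Across genes, which are not independent replicates, log2 fold changes at 1 h and 3 h had r = 0.604 (covariance 0.0661), those at 3 h and 6 h r = 0.694 (covariance 0.137), and those at 6 h and 24 h r = 0.467 (covariance 0.0904). At 1 h and 24 h r was -0.0047 (covariance -0.00050). Unchanged groups simulated against a shared control group gave a mean r of 0.501 (range -0.193 to 0.920) and a mean covariance of 0.00516 (highest 0.0123). That control group was drawn at random from all 15 libraries and was not the DMSO group itself. At 1 h and 3 h 1304 genes were higher at both times against 449 for independent lists, and 712 were lower at both against 290.2. At 3 h and 6 h 2565 were higher at both against 1328, and 2321 lower at both against 941. At 6 h and 24 h 3824 were higher at both against 2991, and 1035 lower at both against 448. At 1 h and 24 h 858 were higher at both against 1012, and 227 lower at both against 138. The 3 DMSO libraries cannot be divided into parts of at least 2, so part of the excess may come from the shared controls.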

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

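The tests of handling at 1 h, of transcript length for EP300 and CREBBP, of genomic DNA and depth for the silent genes, and all counts of other splits were chosen only after the result was seen. With equal groups in 1 fit, limma's direct contrast of 2 times has the same SE as each time against DMSO. For a gene called in opposite directions at 2 times, its passing therefore follows from the calls and adds no support. The genes and lists below were called in opposite directions at 2 times, and the direct contrast between these times also passed. Among the regulators these were XBP1 (0.35 at 3 h, -0.45 at 24 h, difference -0.80), IKZF1 (-1.08 at 3 h, 0.23 at 24 h, difference 1.31), CCND2 (0.33 at 1 h, -0.31 at 24 h, difference -0.64) and TNFRSF17 (0.15 at 3 h, -1.28 at 24 h, difference -1.44). The IKZF1 call at 24 h was lost without DMSO replicate 2 (0.13) or KB528 replicate 1 (0.21), without a filter and with median-ratio and spike-in scaling, and its sign changed after length correction (-0.025). That of TNFRSF17 at 3 h was lost without DMSO replicate 2 (0.15), DMSO replicate 3 (0.11) or KB528 replicate 2 (0.071), without a filter, without a variance trend, with only the compared groups and with median-ratio scaling, and its sign changed under spike-in scaling (-0.068). Spike-in scaling also ended the calls of XBP1 and CCND2 at both times. Of genes named for their size, CDKN1A (3.05 at 1 h, -1.93 at 24 h, difference -4.97), ATF3 (2.88 at 1 h, -1.15 at 6 h, difference -4.03) and FOSB (2.80 at 1 h, -1.86 at 24 h, difference -4.66) turned from higher to lower. So did NR4A1 (2.50 at 1 h, -0.52 at 24 h, difference -3.03), BBC3 (2.05 at 1 h, -1.27 at 6 h, difference -3.33), TFAP2C (0.31 at 1 h, -2.53 at 6 h, difference -2.83) and BHLHA15 (0.34 at 1 h, -1.96 at 24 h, difference -2.30). The opposite turn was made by DDIT4 (-1.65 at 1 h, 0.69 at 6 h, difference 2.34), SERTAD3 (-1.25 at 1 h, 0.34 at 24 h, difference 1.60), ZNF217 (-1.75 at 3 h, 0.45 at 24 h, difference 2.19) and DUSP5 (-2.39 at 3 h, 0.15 at 24 h, difference 2.54). It was also made by PRAMEF4 (-2.28 at 3 h, 0.25 at 24 h, difference 2.53), HMOX1 (-0.19 at 1 h, 1.91 at 24 h, difference 2.10), PEX5L (lower at 3 h, 1.84 at 24 h, difference 2.84), ABTB1 (-0.36 at 3 h, 1.69 at 24 h, difference 2.05) and PKN3 (-0.45 at 3 h, 1.62 at 24 h, difference 2.07). The times at which these genes were not named were not recomputed under the alternatives.

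Lists that turned are given with their median log2 fold changes and the adjusted p of camera's direct contrast. They were MYC targets (0.18 at 3 h, -0.27 at 24 h, adjusted p = 1.37e-20, or adjusted p = 0.158 with an estimated correlation), ER chaperones and secretion (0.14 at 1 h, -0.49 at 24 h, adjusted p = 3.23e-21, or adjusted p = 0.0931 with an estimated correlation) and the ATF4 response (0.13 at 1 h, -0.14 at 6 h, adjusted p = 1.51e-05, or adjusted p = 0.424 with an estimated correlation). The others were immediate early genes (0.53 at 1 h, -0.31 at 24 h, adjusted p = 2.33e-09, or adjusted p = 0.342 with an estimated correlation), mitosis and G2/M (-0.18 at 3 h, 0.67 at 6 h, adjusted p = 5.7e-20, or adjusted p = 0.269 with an estimated correlation), proteasome subunits (-0.063 at 1 h, 0.21 at 6 h, adjusted p = 9.3e-05, or adjusted p = 0.424 with an estimated correlation) and heat shock (-0.20 at 3 h, 0.38 at 6 h, adjusted p = 1.11e-06, or adjusted p = 0.353 with an estimated correlation). The call of Proteasome subunits at 1 h was lost without DMSO replicate 1 (adjusted p = 0.0859) or 2 (adjusted p = 0.0609), and that of Proteasome subunits at 6 h without DMSO replicate 3 (adjusted p = 0.0691), with adjusted p between 0.000569 and 0.908 at 1 h and between 9.31e-05 and 0.663 over all alternatives at 6 h.

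Outside the tested genes, the ERCC share of TPM exceeded the highest DMSO library (14.8%) in 1 h replicate 3 (15.2%), 3 h replicate 1 (16.6%) and 3 h replicate 3 (16.3%). Untested genes above 0 TPM numbered more than in the highest DMSO library (5782) in 1 h replicate 2 (5887), 3 h replicate 3 (5835), 6 h replicate 1 (5860), 6 h replicate 3 (6098) and 24 h replicate 1 (6717).

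The rise of p53 targets at 1 h was weighed because 20 of 25 rose together within 1 h of an acetyltransferase inhibitor. Transcript length and expression level are argued against, since the list's median of 0.56 lay at percentile 100 of 10000 lists matched on both, whose highest median was 0.16. Scaling is argued against too, since the lowest median under the other scalings and the length correction was 0.49. Handling of the 1 h cultures stays open and cannot be told apart from the drug, because the DMSO libraries were taken at 1 time; 26.9% of called immediate early genes (7 of 26) were lower, more than a response to handling was predicted to give, but a partial response remains possible. An effect of KB528 itself is the biological explanation the design names, and it may be the cause, but it was not tested apart from handling.

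EP300, the target's own gene, and its relative CREBBP rose together at 6 h. Transcript length is argued against, since of 514 other genes with similar transcripts (median 0.23, SD 0.46) 0.389% (2 genes) reached the lower of the 2 fold changes. After length correction, the lower of the 2 shares of the log2 fold change that remained was 88.4%. Scaling is argued against, since the lowest log2 fold change under median-ratio and spike-in scaling was 0.97. Reads shared between these related genes were not tested, so this stays open. An effect of KB528 is the biological explanation the design names, and it was not tested apart from time in culture.

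In 24 h replicate 1, 6 h replicate 1 and 6 h replicate 3, 1114, 786 and 860 of the 6972 genes at 0 in DMSO had reads, against 397 to 650 in the other treated libraries. Depth is argued against, since the highest relative depth of the 3 was 0.951, no higher than the median library. Traces of genomic DNA stay open, since over the libraries of the same group, among 4526 genes with a length, the excess per kilobase in the longest genes was at least 1.08 times that in genes of middle length (1.90, 1.08 and 1.23, or 1.66, 0.971 and 1.09 over 12 other libraries), but that in the shortest genes was 2.59, 1.74 and 2.06 times it, less even than such traces would give. Other cells were predicted to raise a marker list above every other library, which 0 of 5 lists did in all 3 libraries, but 3 of the lists sum in DMSO to more than the largest excess (285 TPM), T cell markers 502, fibroblast markers 637 and epithelial markers 415 TPM, so a small share stays open. Loss of silencing was not tested and stays open; the other libraries of these groups had 466 and 490 such genes at 24 h and 406 at 6 h.

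With 3 libraries against 3 there are 10 splits, so the share with a result as large is never under 0.1. For genes, 1 of 10 splits, the real one, was as large in each comparison. The real counts stood against a highest other count of 0 at 1 h (2710), 6 h (8272) and 24 h (8564), 539 at 3 h (6827), and 0 from 1 h to 3 h (5645), 3 h to 6 h (6722) and 6 h to 24 h (8047). For lists, 1 of 10 splits was as large at 1 h (14, highest other 12), 6 h (21, highest other 20) and 24 h (22, highest other 17), and 2 of 10 at 3 h (15, highest other 15). Over the time course 1 of 100 drawn splits, the real one, reached 11229 genes, and the highest other gave 4610. The real one was among the 100 by design, and the others mixed the groups, which widens the spread within groups and lowers their counts. A random grouping of the 15 libraries is argued against for the time course only. For the single comparisons 10 splits are too few to decide, and for lists at 1 h, 3 h and 6 h other splits came close to the real count. Chance differences between cultures are not excluded for any result, since the libraries of a group may be technical replicates.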

How the results depend on the processing

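Scaling to the spike-ins, TPM without spike-ins, length correction and removal of small RNA genes were chosen after the data were seen; the other alternatives were planned. Among 373 results for a gene at a time, the direction and the side of the threshold were the same for 373 with a pseudocount of 0.1, 371 with TPM without spike-ins, 369 without a variance trend, 368 without small RNA genes, 365 with median-ratio scaling, 365 with only the compared groups, 363 with length correction, 359 without a filter, 342 at a filter of 5 TPM, where fewer genes are tested, and 264 with spike-in scaling. Leaving out 1 library left 2159 results the same, with 73 calls lost and 6 gained. Among 128 list results, 128 were the same with TPM without spike-ins, without a trend and without small RNA genes, 127 with a pseudocount of 0.1 and with only the compared groups, 121 at a filter of 5 TPM, 120 with length correction, 118 without a filter, 117 with median-ratio scaling and 105 with spike-in scaling. Leaving out 1 library left 752 the same, with 10 lost and 6 gained.

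Counts of changed genes moved by over 1.5 times with spike-in scaling, to 471 at 1 h, 2934 at 3 h, 5113 at 6 h, 3096 at 24 h, 2151 from 1 h to 3 h and 3677 from 6 h to 24 h. With only the compared groups in the fit, and so fewer samples, 1723 changed at 1 h. Why the spike-in factors varied within groups is a cause that was not tested. By leaving out 1 library the counts ranged from 1818 to 3920 at 1 h (3920 without DMSO replicate 3), 6108 to 6808 at 3 h, 7672 to 8322 at 6 h, 7893 to 8717 at 24 h, 4893 to 5522 from 1 h to 3 h, 5774 to 6548 from 3 h to 6 h, 7406 to 7574 from 6 h to 24 h and 11028 to 11364 over the time course. Lists ranged from 13 to 15 at 1 h, 15 to 17 at 3 h, 19 to 20 at 6 h and 22 to 22 at 24 h.

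With an estimated correlation camera called 0 lists at 1 h, 0 at 3 h, 0 at 6 h and 0 at 24 h, and at an unadjusted p under 0.05 it gave 1, 2, 4 and 8. By fry, which compares no list with other genes, 11, 22, 22 and 24 lists passed, 11 higher and 0 lower at 1 h, 8 and 14 at 3 h, 9 and 13 at 6 h and 12 and 12 at 24 h. Fry pointed the other way at 24 h for the ATF4 response (adjusted p = 0.704), p53 targets (0.017), heat shock (0.020) and housekeeping genes (0.020), since fry sets a list against DMSO and camera sets it against the other genes.

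Signs changed under spike-in scaling for TNFRSF17 at 3 h (-0.068), RPL4 at 6 h (0.034) and RPS26 at 6 h (0.033), under median-ratio scaling for CCND2 at 6 h (-0.12), and under length correction for CCND2 at 6 h (-0.095), IKZF1 at 24 h (-0.025) and IKZF3 at 24 h (-0.13). The cause was not tested. The fold change correlation between times 1 h and 3 h was 0.559 without small RNA genes. The fold change correlation between times 3 h and 6 h was 0.715 and 0.721 with length correction and without small RNA genes, and the fold change correlation between times 6 h and 24 h was 0.490 at a filter of 5 TPM. Leaving out 1 library gave 0.576 to 0.625, 0.678 to 0.701, 0.460 to 0.483, and -0.023 to 0.064 between 1 h and 24 h.

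The replicate numbers were not taken to pair the samples. Over 30 pairs of libraries with the same number, deviations from the group means correlated between -0.157 and 0.430 (mean 0.0288, against -0.0145 for other pairs), 7 of them over 0.1, and 8 of 15 libraries correlated best with their own number. Such pairs of DMSO and 6 h correlated at 0.136, 0.152 and 0.148, and those of DMSO and 1 h at -0.032, -0.069 and 0.016. Pairing between some groups is therefore not excluded. With the replicate block 2926 genes changed at 1 h, 6950 at 3 h, 8384 at 6 h, 8636 at 24 h, 5777, 6847 and 8149 between consecutive times and 11286 over the time course, and 14, 16, 21 and 22 lists were called. The block changed the call of IRF4 and MAF at 1 h and of ribosomal proteins at 3 h, and of no other named gene or list. Depth limits the low genes, since 1 read in 1000 bases is worth up to 0.0458 TPM.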

Other observations

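The keratin, metallothionein and NRF2 target families and the test of the size of the depth effect were chosen only after the data were seen; the tests of gene span and of relative depth were not. Of 14 tested keratin genes, which encode intermediate filaments of epithelial cells, 4 fell and 10 did not pass at 1 h, 13 fell and 1 rose at 3 h and at 6 h, and 8 fell and 3 rose at 24 h, with medians of -0.070, -0.27, -0.60 and -0.35. No test of the family as a set was run. Under spike-in scaling 0, 7, 7 and 6 fell, and the median stayed below 0 under every scaling. KRT16 fell from 140.0 ± 4.56 to 33.2 ± 1.66 TPM at 6 h (log2 fold change -2.04) and KRT80 from 14.2 ± 2.09 to 2.74 ± 0.322 TPM. KRT10 rose by 0.49 at 6 h. KRT6C, KRT6B, KRT81 and KRT86 have near-identical copies with which reads may be shared, which was not tested, and are uncertain.

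Metallothionein genes, which encode metal-binding proteins and are a multi-copy family whose reads are uncertain, fell at 24 h in 6 of 7 cases (5 under spike-in scaling), with a median of -0.83. MT1G went from 64.5 ± 4.23 TPM in DMSO to 17.6 ± 3.46 TPM at 24 h. MT1X was above DMSO at 6 h (0.91, 189 ± 8.60 against 100.4 ± 8.55 TPM) and below it at 24 h (-0.79). Of 19 targets of NRF2, the transcription factor of the oxidative stress response, 10 rose and 4 fell at 24 h with a median of 0.080. The median turned negative with median-ratio scaling (-0.12, with 7 higher and 10 lower) and length correction (-0.025, with 7 and 9), so the family as a whole has no stable direction, while AKR1C3 rose from 49.6 ± 2.98 to 142 ± 1.34 TPM and FTL, the ferritin light chain gene, fell by 0.53 at 24 h.

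Small nucleolar RNA genes took 0.523% ± 0.042 of gene TPM in DMSO, 0.892% ± 0.032 at 1 h, 0.958% ± 0.044 at 3 h, 0.570% ± 0.0048 at 6 h and 0.413% ± 0.0090 at 24 h (n = 3). Exact two-sided permutation tests against DMSO gave p = 0.1, 0.1, 0.3 and 0.1, where 0.1 is the smallest p the design allows. By limma 122 of 185 of these genes were higher and 1 lower at 1 h, 132 and 1 at 3 h, 46 and 18 at 6 h, and 8 and 66 at 24 h. Relative depth was weighed, since within groups the share went down with depth over 15 libraries (Spearman rho -0.704, permutation p = 0.00346, and Pearson r -0.590, permutation p = 0.00983). Pearson r was -0.737 without the 2 libraries farthest from the median depth. The within-group slope gives only 8.29% of the 1 h difference and -0.27% of the 3 h difference. Mean relative depth was 1.02 ± 0.089 in DMSO and 1.02 ± 0.039 at 3 h. These values argue against depth as the main source of the rise at 1 h and 3 h. Since snoRNA are not polyadenylated and mostly lie in introns, reads from introns of unspliced RNA might add to them; this was not tested.

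A hypothesis was that KB528 lowers long genes first, as a loss of elongation would. The prediction was a correlation below a negative cut, set for 1 h only. It failed at 1 h, since among genes of similar transcript length the Spearman correlation of log2 fold change and gene span over 10662 genes was 0.0898. At 3 h the correlation was -0.107, just past that cut and in the direction the hypothesis predicts. No prediction was set for 3 h, so the hypothesis stays open there. At 6 h and 24 h the correlation was -0.085 and 0.069. Genes are not independent replicates, and no p is given. Apart from the counts of other splits of the libraries for 12 results, 12 explanations were tested across the closing parts, 3 for each weighed pattern, 1 for gene span and 2 for snoRNA.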
